A study of Mus musculus with 6 samples.

How the data were processed

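Gene expression was measured in hearts of 8-week-old mice on Affymetrix GeneChip arrays, with 1 array per mouse. Of the 6 arrays, 3 came from mice with both transgenes (DNMTs-Tg, replicates 1, 5 and 6) and 3 from wild-type mice (replicates 1, 4 and 6). Groups, replicate numbers, age and sex were taken from the sample labels. Per the labels' protocols, hearts were frozen in liquid nitrogen, total RNA was purified with a kit for fibrous tissue, and biotin-labelled material was made by in vitro transcription after a single cycle of cDNA synthesis.

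The authors deposited 1 value per probe set and array. The deposited values were taken as log2 signals because they lay between 2.06 and 14.7 on every array, none of them negative. The array medians of 5.28 to 5.33 show that the arrays had been put on a common scale, but the background correction, the normalization and the software are not given in the sources used here. No detection calls were used, so whether a dim probe set was above background is unknown. The table held 45101 probe sets, of which 34945 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none, 51 of them control probe sets. The other 13 of the 64 control probe sets carry a symbol and were left out. Symbols were updated through gene identifiers to the mouse annotation GRCm38.p6, which matched 34754 of the probe sets and was otherwise used only for chromosomes and for the order of genes.

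The values were analysed as deposited, without further normalization. A probe set was kept where at least 3 of the 6 arrays lay above the 40th percentile of their own array, which kept 27377 probe sets, 23669 of them with 1 symbol. Each gene was represented by its kept probe set with the highest mean over the 6 arrays, which left 13634 genes. Differences were tested 2-sided with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values given for genes come from that model, or from limma fits with another setting or without an array where that is said. A gene whose values in a group all lay at or below the 40th percentile of their array was treated as dim there, and its fold is given as at least the ratio of the brighter group's mean to the mean of, per array, that percentile. This floor was set by the analysis and is no measured background. Every probe set of Dnmt3a and Dnmt3l was also tested without the filter.

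The genes named are the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out clone names and sex-linked genes, with Dnmt3a and Dnmt3l always included. From each gene list, up to 6 members past the threshold were named, or otherwise the 2 with the smallest p. In total 90 genes were named by this rule, 34 of them with more than 1 kept probe set. The kept probe sets of 5 of these genes, Dnmt3a, Meg3, Rian, Eif4ebp1 and Plk2, differed in sign. Probe sets of Dnmt3l, Cyp2b10, Cd1d1, Fmo2, Hspe1, S100a8 and Eif4ebp1 carry a platform suffix for probes shared with other transcripts, so their values may include signal from related genes.

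The 35 gene lists covered DNA methylation, imprinting, cardiac and metabolic programmes, stress and immune pathways and markers of other cell types. All but the list of sex-linked genes were tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 34 lists. Camera with an estimated correlation and limma's fry were run as alternatives. Per-array list values are means over the measured members, relative to the wild-type mean. Changed genes were tested for their chromosome with Fisher's exact test over 21 chromosomes. Promoter CpG content was to be compared as well, but that needs a genome sequence and was not run.

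The steps were tested on simulated data with the 13634 genes and 3 arrays per group of this comparison. Of 100 genes changed 2-fold 74% were recovered and of 100 changed 4-fold 93%, with 0 wrong signs and 5 unchanged genes called. Of 20 shifted lists 20 were called, and of 100 unshifted lists 0. The simulated genes varied independently of each other, with the same SD in both groups. The gene counts therefore do not cover variation shared by the genes of an array or a group with a larger spread. Nor do the list counts cover lists of correlated genes. In the real data the estimated correlation reached 0.81 for oxidative phosphorylation. The number of arrays limits the precision, and an exact permutation test of 3 against 3 arrays cannot give a p below 0.1.

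The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The alternatives were quantile normalization, a common median, other filters, the mean of a gene's probe sets, other variance models, array weights, the label number as a replicate block, other thresholds, each probe set on its own, and leaving out each array in turn. Replicate numbers 1 and 6 occur in both groups but belong to different mice, so arrays were not treated as pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.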

Results

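Expression was compared in whole hearts of 3 DNMTs-Tg mice and 3 wild-type mice, all 8 weeks old. DNMTs-Tg mice carry transgenes for DNMT3A2, a short form of the de novo DNA methyltransferase DNMT3A, and for DNMT3L, its catalytically inactive partner, expressed in many somatic tissues. The study asked which genes lose expression in the heart when both proteins are present. DNA methylation was not analysed here. The 6 arrays had median log2 signals of 5.28 to 5.33, and 13634 genes were tested.

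The transgene Dnmt3l separated the genotypes on every array. Its log2 signal was 12.29 ± 0.09 (SD, n = 3) in DNMTs-Tg and 5.31 ± 0.15 (SD, n = 3) in wild-type hearts, a 126-fold difference (limma, adjusted p = 1.06e-06). Dnmt3a was measured by 5 probe sets that did not move together. The brightest over the 6 arrays rose by 1.02 ± 0.22 (log2, SE, n = 3 per group), from 8.66 ± 0.40 to 9.68 ± 0.23 (SD). In wild-type hearts another was brighter, at 9.07 ± 0.48, so the choice of the risen probe set for the gene rested on its DNMTs-Tg values. The adjusted p of the risen probe set was 0.0467 among the genes tested and 0.0563 when every probe set was tested without the filter. The remaining probe sets differed by -0.28, -0.28, -0.11 and -0.09, and none of them passed the threshold. Which of the 5 lie within the transgene is not known here, and with the mean of the kept probe sets the difference was 0.050 (adjusted p = 0.906). Leaving out DNMTs-Tg replicate 5 ended the Dnmt3a call (0.88, adjusted p = 0.142), as did leaving out wild-type replicate 1 (0.93, adjusted p = 0.175) or wild-type replicate 4 (0.87, adjusted p = 0.157).

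The labels describe 5 mice as female and wild-type replicate 6 as male. Y-linked RNA was present on 5 arrays and the X-inactivation transcript Xist on only 1, that of wild-type replicate 4. Eif2s3y, a Y-linked gene, had log2 signals of 9.41 to 9.52 on those 5 arrays and 3.32 on the array of wild-type replicate 4, whereas Xist had 4.52 to 4.96 on the 5 arrays and 10.1 on that array. The sex-linked RNA thus differed from the label in 4 mice, the 3 DNMTs-Tg mice and wild-type replicate 1. The genotype comparison was therefore between 3 arrays of male type and a group of 2 arrays of male type and 1 of female type.

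**Figure D1:**
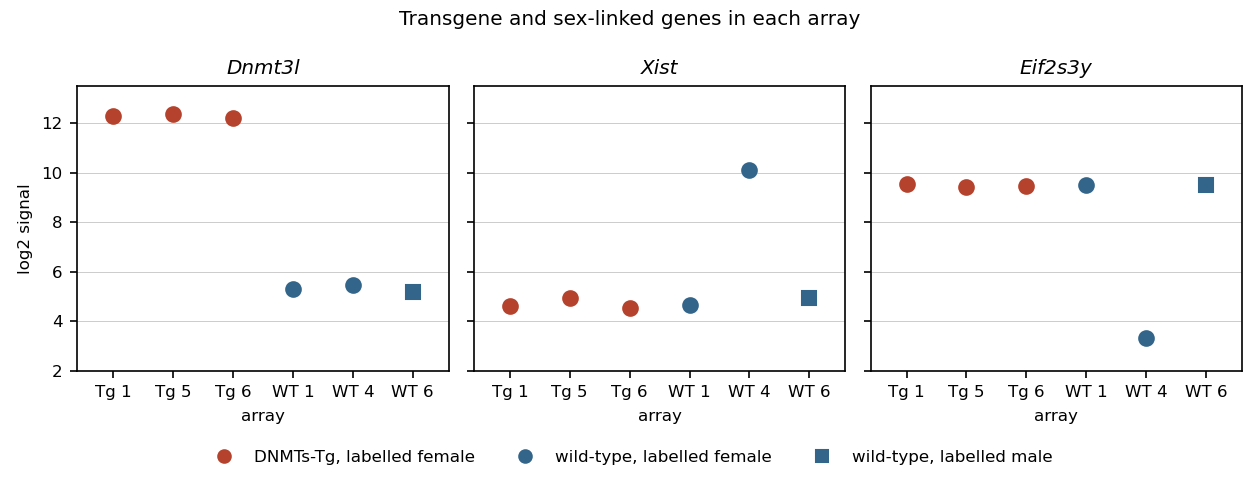
Log2 signal of Dnmt3l, Xist and Eif2s3y on each array, with 1 point per mouse, colour for genotype and shape for the sex in the labels. Dnmt3l lies at 12.19 or above in the 3 DNMTs-Tg hearts and at 5.48 or below in the 3 wild-type hearts, and only wild-type replicate 4 has Xist at 10.1 and Eif2s3y at 3.32.

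In DNMTs-Tg hearts 735 genes changed, of which 306 rose and 429 fell (58.4% lower). The falls included Bdh1, the mitochondrial enzyme that interconverts the ketone bodies beta-hydroxybutyrate and acetoacetate. The rises included Myh7, the slow beta-myosin heavy chain. Nmrk2, a kinase of NAD synthesis from nicotinamide riboside, and Dct, an enzyme of melanin synthesis, rose as well. At least 2-fold changes were seen for 132 of the genes that rose and 193 that fell, and at least 4-fold changes for 38 and 37. All 735 had groups that did not overlap, which a call with 3 arrays per group nearly requires. Over all genes tested, 4760 (34.9%) had no overlap, and the median log2 change was 0.0055. Chance gives 10% without overlap on average over the 10 splits of the arrays, but genes vary together, so 1 split can lie far from that. The first principal component held 64% of the variance and spread the DNMTs-Tg arrays. Their scores were -53.0, -21.1 and -4.34 for replicates 1, 5 and 6, while the wild-type scores were 24.6 to 27.8. The log2 difference between the 3' and 5' Gapdh probe sets, a measure of RNA integrity, was 0.66 ± 0.12 (SD, n = 3) in DNMTs-Tg and 0.43 ± 0.06 (SD, n = 3) in wild-type arrays (exact permutation test, 2-sided p = 0.1, the smallest possible). That of Actb was 1.12 ± 0.25 and 1.15 ± 0.09 (exact p = 0.8). The number of calls changed strongly with single arrays left out. Without DNMTs-Tg replicate 5 there were 50 rises and 92 falls, and without DNMTs-Tg replicate 6 there were 815 and 789. Without wild-type replicate 1 there were 44 and 79, without wild-type replicate 4 there were 52 and 110, and without wild-type replicate 6 there were 74 and 128. Without DNMTs-Tg replicate 1, the array farthest from wild-type, 447 rose and 620 fell. All 735 genes kept their direction in each of these 6 fits, and 105 of them (34 rises and 71 falls) were called in every one.

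Among the rises, the cytochrome P450 gene Cyp2b10 followed Dnmt3l in size, with 9.64 ± 0.23 (SD, n = 3) in DNMTs-Tg against 5.48 ± 0.57 in wild-type hearts (log2 change 4.16 ± 0.28, SE, adjusted p = 0.00107). Dct rose by 4.12 ± 0.22 (adjusted p = 0.000517) and Nmrk2 by 3.95 ± 0.30 (adjusted p = 0.00158). Myh7 rose by 3.66 ± 0.63 (adjusted p = 0.0245), from 10.80 ± 1.40 to 14.46 ± 0.40 (SD, n = 3), a measured 12.6-fold. Its probe set was the brightest of all on the array of DNMTs-Tg replicate 1 and lay 0.04 (log2) below the brightest on that of replicate 5, so saturation may have made this fold too small. With 1 array left out the fold ranged from 7.25 (without wild-type replicate 6) to 17.9 (without wild-type replicate 4), and the call was kept in 4 of 6 fits. Tceal7 was at least 7.28-fold higher (adjusted p = 0.00524), since its wild-type signals lay below the 40th percentile of their arrays. The neuronal potassium-chloride cotransporter gene Slc12a5 rose by 3.09, the cytoskeletal linker gene Gas2l3 by 3.08, the hyaluronan receptor gene Cd44 by 2.82, the amino acid transporter gene Slc38a4 by 2.80, the T-box factor gene Tbx15 by 2.78 and Rnd1 by 2.58, with adjusted p from 0.00664 for Slc38a4 to 0.0336 for Rnd1. Of these 12 rises, 6 (Dnmt3l, Cyp2b10, Dct, Nmrk2, Tceal7 and Slc38a4) were called with any 1 array left out.

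Bdh1 showed the largest fall, from 11.10 ± 1.20 (SD, n = 3) in wild-type to 4.13 ± 0.54 in DNMTs-Tg hearts, where it lay below the 40th percentile of each array, so that it was at least 85.3-fold lower (adjusted p = 0.00224). With 1 array left out this bound ranged from 65.5 to 138, the highest without wild-type replicate 6. Bex1 was at least 11-fold lower (adjusted p = 0.000628), and the ribosomal protein gene Rps4l at least 8.74-fold lower (adjusted p = 0.00458). The carbonic anhydrase gene Car3 was at least 7.91-fold lower (adjusted p = 0.00255), the dihydrodiol dehydrogenase gene Dhdh at least 6.88-fold lower (adjusted p = 0.000517) and C1qtnf4 at least 6.16-fold lower (adjusted p = 0.000689). The log2 change was -3.81 ± 0.29 (SE) for Dcaf12l1 (adjusted p = 0.00160) and -3.21 ± 0.57 for the glutathione transferase gene Gstk1 (adjusted p = 0.0272). Dcaf12l1 lay below the 40th percentile in DNMTs-Tg replicates 1 and 5 and just above it in replicate 6 (4.75 against 4.72), so its size is uncertain. Without replicate 6 it was at least 9.50-fold lower. The log2 change was -2.79 for Lgi1, -2.78 for the liver glycogen phosphorylase gene Pygl, -2.76 for the angiopoietin gene Angpt1 and -2.71 for the acylpeptide hydrolase gene Apeh. These had adjusted p from 0.000183 for Apeh to 0.0184 for Lgi1. Of the 12 falls, 9 (all but Gstk1, Lgi1 and Angpt1) were called with any 1 array left out.

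**Figure D2:**
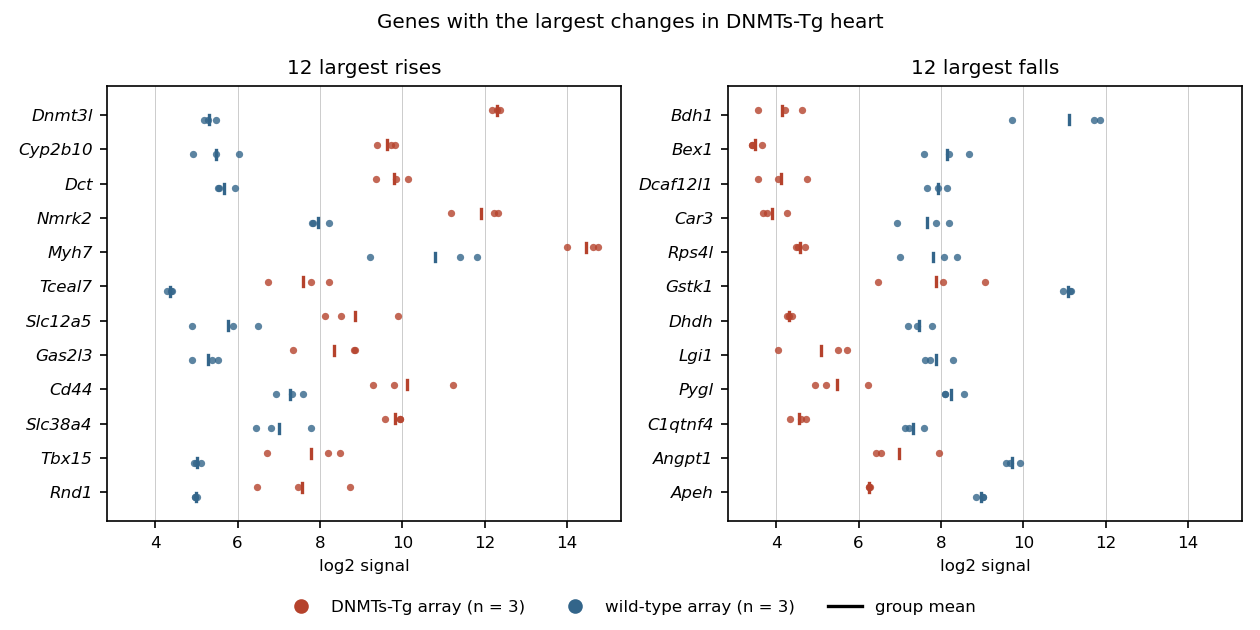
Log2 signal of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), with 1 point per array, 3 per genotype, and a vertical bar at each group mean. The groups do not overlap for any of these genes, and Bdh1 drops from a wild-type mean of 11.10 to 4.13 in DNMTs-Tg hearts.

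Of the 34 gene lists tested, 5 stood higher and 2 lower in DNMTs-Tg hearts by camera with its preset correlation, and 0 of them passed with an estimated correlation, where the lowest adjusted p was 0.924 and 0 lists had an unadjusted p under 0.05. By limma's fry 0 of the 7 lists passed in direction, where DNA methylation machinery, which holds the transgenes, was the 1 list past the threshold, and 19 lists passed for change either way. The 34 lists held 613 measured genes, of which 39 changed, against 735 of all 13634 genes tested. Unadjusted p was under 0.05 for 3543 of those 13634 genes, and the counts of such members in single lists are to be read against that share. Of the 39 changed list members, 8 (Dnmt3l, Mbd1, Ppp1r9a, Ccnd2, Eda2r, Nmrk2, Pam and Stard10) were called with any 1 array left out. The other 31 were called in 2 to 4 of those 6 fits. The list of fetal and stretch-induced cardiac genes, which are re-expressed in stressed myocardium, had a median log2 change of 0.81, with 17 of 20 members above 0 (adjusted p = 0.00328 and, with an estimated correlation, adjusted p = 0.924). Myh7 was the member that rose over all genes tested, and 3 rose adjusted over the list alone. Nppa (0.86 ± 0.92, SE, adjusted p = 0.583) and Nppb (0.07 ± 0.63, adjusted p = 0.957), which the naming rule did not pick, did not pass. List values were 1.48, 0.95 and 0.24 in DNMTs-Tg replicates 1, 5 and 6 and -0.13 to 0.12 in the wild-type arrays. The 24 genes of the adult sarcomere and calcium handling had a median of 0.01 (adjusted p = 0.813), with 0 members past the threshold, 6 at unadjusted p under 0.05 and 2 rising adjusted over the list alone. Actn2 (0.41, adjusted p = 0.0568) and Mybpc3 (0.34, adjusted p = 0.0606) came closest, and both passed with the filter at the 60th percentile (adjusted p = 0.0495 for each).

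All 26 measured genes of oxidative phosphorylation had a change below 0, with a median of -0.25 (adjusted p = 2.24e-05 and, with an estimated correlation, adjusted p = 0.924), but 0 members passed limma's threshold on their own, over all genes or adjusted over the list alone, and 10 had an unadjusted p under 0.05. Cox7a1, a cytochrome c oxidase subunit, differed by -0.93 (adjusted p = 0.0566) and Ndufa4 by -0.31 (adjusted p = 0.0694). In fatty acid oxidation 3 of 22 members lay above 0, the median was -0.31 (adjusted p = 0.00746 and, with an estimated correlation, adjusted p = 0.929), and again 0 members passed over all genes or adjusted over the list alone, with 7 at unadjusted p under 0.05. Acadm differed by -0.70 (adjusted p = 0.110) and Echs1 by -0.72 (adjusted p = 0.116). Without DNMTs-Tg replicate 1 the differences were -0.42 and -0.43. List values in DNMTs-Tg replicates 1, 5 and 6 were -0.72, -0.21 and -0.05 for fatty acid oxidation and -0.48, -0.18 and -0.12 for oxidative phosphorylation. In the same arrays macrophage markers stood at 1.40, -0.06 and 0.02 and fibroblast markers at 0.87, 0.08 and 0.04. Fasting and PPAR target genes did not pass (median 0.10, mean -0.03, tested as lower, adjusted p = 0.604), with 1 of 17 members falling, the mitochondrial carrier gene Slc25a34 (-1.17, adjusted p = 0.0454, and 0.0506 under quantile normalization), and 2 adjusted over the list alone. Glycolysis genes did not pass either (median -0.01, adjusted p = 0.902), with 0 of 20 members past the threshold or adjusted over the list alone and 1 at unadjusted p under 0.05. The members with the smallest p were Pfkm at -0.86 (adjusted p = 0.123) and Pgam2 at 0.23 (adjusted p = 0.227). Without DNMTs-Tg replicate 1 Pfkm stood at -0.50.

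Extracellular matrix genes lay higher, with 26 of 28 members above 0 and a median of 0.86 (adjusted p = 8.55e-05 and, with an estimated correlation, adjusted p = 0.924). Here too 0 members passed over all genes or adjusted over the list alone, and 12 had an unadjusted p under 0.05, all of them higher. Timp1, an inhibitor of matrix metalloproteases, differed by 2.90 ± 0.77 (SE, adjusted p = 0.0758) and the basement membrane collagen gene Col4a2 by 0.87 ± 0.24 (adjusted p = 0.0806). DNMTs-Tg replicate 1 stood apart, with a list value of 1.85 against 0.59 and 0.31 in replicates 5 and 6, and wild-type replicate 6 reached 0.34. The same array stood apart for macrophage and myeloid markers, with 1.40 against -0.06 and 0.02, and for fibroblast markers, with 0.87 against 0.08 and 0.04. Those marker lists did not pass (adjusted p = 0.0817 and 0.344). The macrophage list passed by camera with no filter (adjusted p = 0.0132), with the mean of probe sets (adjusted p = 0.0349) and in 2 of 6 fits with 1 array left out. Without DNMTs-Tg replicate 1 its adjusted p was 0.451. Over the settings other than leaving out an array its adjusted p ranged from 0.000214 to 0.961. In the macrophage list 0 of 21 members passed and 3 had an unadjusted p under 0.05, with Ccr2 at 1.44 (adjusted p = 0.0509) and Lgals3 at 2.16 (adjusted p = 0.0792). Ccr2 differed by 0.10 under quantile normalization (adjusted p = 0.658) and by 0.93 with the mean of its probe sets, where it passed (adjusted p = 0.0234). It has 3 kept probe sets, and the brightest may be another one after quantile normalization. The 0.10 therefore need not be a change in the same probe set. In the fibroblast list 1 of 20 fell, Ogn (-0.98, adjusted p = 0.0284). Adjusted over the list alone, 0 macrophage markers passed and 1 fibroblast marker fell.

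Genes of inflammation and the acute phase had a median change of 0.66 (adjusted p = 0.00413 and, with an estimated correlation, adjusted p = 0.924), and 2 of 21 members rose, over all genes and adjusted over the list alone. These were S100a8 (1.86 ± 0.31, SE, adjusted p = 0.0221) and S100a9 (2.14 ± 0.41, adjusted p = 0.0336), which encode the subunits of calprotectin. List values were 1.54, 0.65 and 0.28 in DNMTs-Tg replicates 1, 5 and 6, with the macrophage markers again at 1.40, -0.06 and 0.02. The interferon and antigen presentation list had a median of 0.35 (adjusted p = 0.00413 and, with an estimated correlation, adjusted p = 0.924), with 3 of 24 members rising and 9 adjusted over the list alone. They were Ifit3 (1.81, adjusted p = 0.0277), Usp18 (1.29, adjusted p = 0.0177) and Ifit2 (1.13, adjusted p = 0.0380). With 1 array left out Ifit3 and Ifit2 were called in 2 of 6 fits, and Usp18, S100a8 and S100a9 in 3. Without wild-type replicate 6 the interferon list no longer passed (adjusted p = 0.0524), and its value in wild-type replicate 4, at 0.37, lay above that of DNMTs-Tg replicate 5, at 0.27.

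The list of p53 targets and senescence genes had a median of 0.46 (adjusted p = 0.00746 and, with an estimated correlation, adjusted p = 0.924), with 5 of 18 members rising over all genes and 8 adjusted over the list alone. Eda2r, a receptor of the tumour necrosis factor family, rose by 2.40 ± 0.26 (SE, adjusted p = 0.00524), Zmat3 by 1.19 (adjusted p = 0.0255), Phlda3 by 1.14 (adjusted p = 0.0378), the exonuclease gene Aen by 1.12 (adjusted p = 0.0154) and Plk2 by 0.99 (adjusted p = 0.0289). The kept probe sets of Plk2 differed in sign, and with their mean it lost its call (0.29, adjusted p = 0.159). Eda2r was called with any 1 array left out, and Zmat3, Phlda3, Aen and Plk2 each in 2 of the 6 fits. List values were 0.82, 0.70 and 0.40 in DNMTs-Tg replicates 1, 5 and 6 and -0.05 to 0.08 in the wild-type arrays. Cdkn1a, a cell cycle inhibitor that is also in the glucocorticoid list, differed by 2.59 ± 0.61 and did not pass (adjusted p = 0.0566).

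Among genes tied to DNA methylation, 3 of 21 machinery genes rose, over all genes and adjusted over the list alone, namely Dnmt3l, Mbd1 and Dnmt3a, the last by 1 of its 5 probe sets. Mbd1, which encodes a methyl-CpG binding protein, rose by 1.43 ± 0.15 (SE, adjusted p = 0.00450). The list as a whole did not pass (median -0.09, mean 0.32, tested as higher, adjusted p = 0.813), and 10 of its 21 members lay above 0. Its directional call by fry (adjusted p = 0.0266) was on a list that includes both transgenes. Of the 27 measured members of the imprinted list, which does not hold every imprinted gene, 1 rose, Peg3 (1.03, adjusted p = 0.0257), and 3 fell. The falls were Ppp1r9a (-1.67, adjusted p = 0.00269) and the noncoding RNAs Rian (-0.95, adjusted p = 0.0324) and Meg3 (-0.69, adjusted p = 0.0381), with 1 rising and 5 falling adjusted over the list alone. The imprinted list did not pass (median -0.18, adjusted p = 0.111), and the kept probe sets of Rian and Meg3 differed in sign. With the mean of the probe sets both lost their calls, at -0.48 for Rian (adjusted p = 0.104) and -0.20 for Meg3 (adjusted p = 0.255), and 1 of the 8 kept probe sets of Meg3 passed. Of 31 germline genes silenced by promoter methylation, 7 were measured after the filter on dim probe sets, and their list did not pass (median -0.24, adjusted p = 0.252). None of the 7 passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05, all of them lower, with Mov10l1 (-0.45, adjusted p = 0.128) and Smc1b (-0.43, adjusted p = 0.103) closest. Without the filter the germline list passed as lower (adjusted p = 0.0238), and over the settings other than leaving out an array its adjusted p ranged from 0.0238 to 0.512.

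Ion channel and conduction genes did not pass as a list (median -0.29, adjusted p = 0.0960), but 3 of 18 changed. The list passed by camera with no filter (adjusted p = 0.0474), with the filter at the 60th percentile (adjusted p = 0.0472) and in 2 of 6 fits with 1 array left out. Over the settings other than leaving out an array its adjusted p ranged from 0.0142 to 0.141. Kcne1, a regulatory potassium channel subunit, rose by 1.97 ± 0.37 (SE, adjusted p = 0.0315), and Kcnd2, a channel of the transient outward current, and Irx5, a transcription factor that represses it, changed by -2.28 ± 0.45 (adjusted p = 0.0350) and -1.35 ± 0.21 (adjusted p = 0.0184). Adjusted over the list alone, 1 rose and 4 fell. Among muscle atrophy and autophagy genes Nmrk2, Ctsl (0.80, adjusted p = 0.0495) and Eif4ebp1 (0.63, adjusted p = 0.0417) rose, of 21 measured, with 7 rising and 2 falling adjusted over the list alone (list adjusted p = 0.0960). Ctsl lost its call under quantile normalization, with a common median, with no filter, with the mean of probe sets and with either other variance model (adjusted p from 0.0503 to 0.0582). Eif4ebp1 lost its call with the mean of its probe sets (0.32, adjusted p = 0.101) and, just above the threshold, without the variance trend. In the unfolded protein and integrated stress response the serine synthesis gene Psat1 (0.92, adjusted p = 0.0209) and the mitochondrial folate gene Mthfd2 (1.00, adjusted p = 0.0341) rose, of 23, with 3 adjusted over the list alone (list adjusted p = 0.0817). Of 19 heat shock proteins 2 fell, Hspa4l (-0.77, adjusted p = 0.0213) and Hspe1 (-0.73, adjusted p = 0.0428, and 0.0516 without the variance trend), with 2 rising and 7 falling adjusted over the list alone (list adjusted p = 0.108). The clock gene Npas2 rose (1.35, adjusted p = 0.0154) and Nr1d1 fell (-0.62, adjusted p = 0.0217), of 19, with 1 rising and 2 falling adjusted over the list alone (list adjusted p = 0.902).

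The cyclin gene Ccnd2 fell by 2.12 ± 0.13 (SE, adjusted p = 0.000689), with all 7 of its kept probe sets past the threshold, and was the 1 cell cycle gene of 22 that changed, over all genes and adjusted over the list alone (list adjusted p = 0.527). In the growth hormone and IGF axis Stat5b fell (-0.86, adjusted p = 0.0348), of 17 measured, with 1 rising and 1 falling adjusted over the list alone (list adjusted p = 0.958). Of 19 antioxidant genes Txn1 fell (-0.64, adjusted p = 0.0265, and -0.42 with adjusted p = 0.0875 with the mean of its probe sets), with 4 rising and 2 falling adjusted over the list alone (list adjusted p = 0.604). None of 20 glucocorticoid targets or 22 immediate early genes passed, over all genes or adjusted over the list alone, and 3 and 4 of them had an unadjusted p under 0.05 (list adjusted p = 0.813 and 0.341). Closest were Cdkn1a and Fmo2 (1.41, adjusted p = 0.0755) among the glucocorticoid targets, and Ier3 (-1.50, adjusted p = 0.0537, and 0.0380 under quantile normalization) and Myc (2.25, adjusted p = 0.0787) among the immediate early genes.

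Markers of other cell types gave few calls. The endothelial gene Vwf rose (1.39, adjusted p = 0.0177), the 1 of 22 endothelial markers to do so, over all genes and adjusted over the list alone (list adjusted p = 0.149). Among 14 atrial markers Pam rose (1.31, adjusted p = 0.00731) and Stard10 fell (-1.34, adjusted p = 0.00284), over all genes and adjusted over the list alone, and the list's median of -0.07 and mean of 0.14 differed in sign (tested as lower, adjusted p = 0.813). Of 11 lung, liver and thymus markers Cd1d1 fell (-1.34, adjusted p = 0.0123), with 2 rising and 1 falling adjusted over the list alone (list adjusted p = 0.799). No skeletal muscle marker of 13 passed over all genes, 5 had an unadjusted p under 0.05 and 4 rose adjusted over the list alone (list adjusted p = 0.491). Acta1, which the cardiac list also holds, stood at 2.19 (adjusted p = 0.0752) and Myoz1 at 0.78 (adjusted p = 0.104). No marker passed, over all genes or adjusted over the list alone, and at most 5 of a list had an unadjusted p under 0.05, for smooth muscle and pericytes (17 measured, list adjusted p = 0.902, Mcam 0.62 and Myh11 -0.49), lymphocytes (14 measured, list adjusted p = 0.372, Cd52 1.23 and Ccl5 0.87) or erythroid cells (9 measured, list adjusted p = 0.514, Rhd 0.52 and Tspo2 0.25). The same held for adipocytes (13 measured, list adjusted p = 0.949, Elovl6 -0.40 and Fasn 0.39) and for neurons and Schwann cells (13 measured, list adjusted p = 0.949, Stmn2 -0.55, which passed with the mean of its probe sets, and Chgb 0.31).

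**Figure D3:**
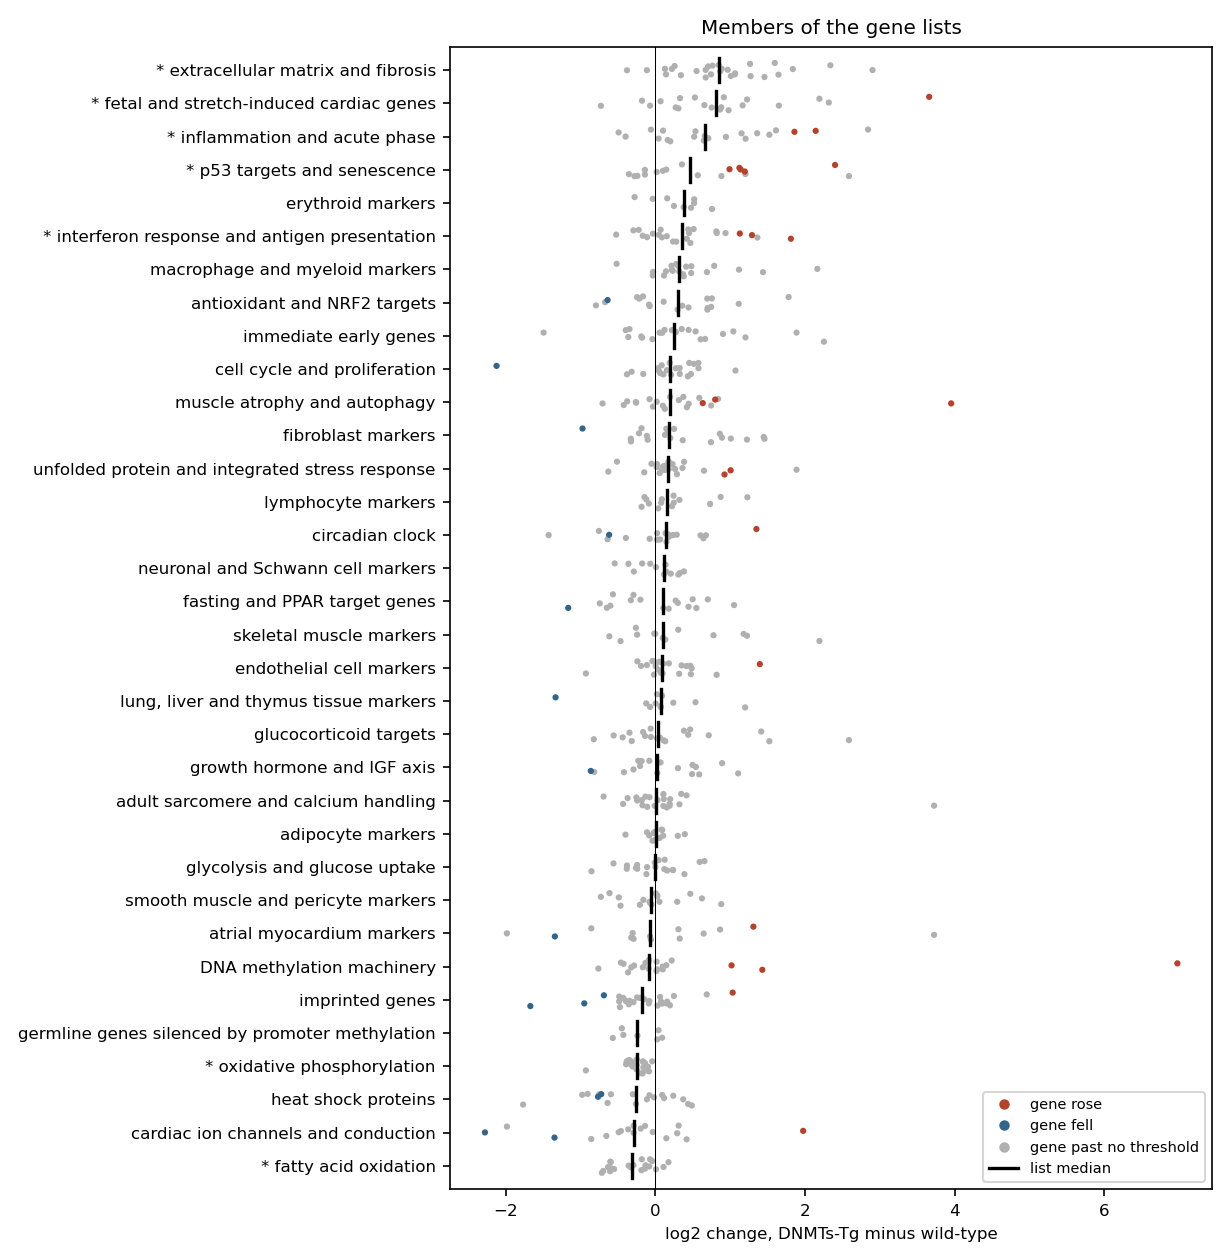
Log2 change (DNMTs-Tg minus wild-type) of each measured member of the 34 gene lists, with 1 point per gene, red for genes that rose and blue for genes that fell, and a vertical bar at each list median. Asterisks mark the 7 lists past the threshold by camera with its preset correlation, from extracellular matrix genes with a median of 0.86 to fatty acid oxidation genes with a median of -0.31.

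No chromosome as a whole stood out for changed genes. The smallest adjusted p of Fisher's exact test over 21 chromosomes was 0.923. Among 13613 genes placed in order, 24 pairs of adjacent tested genes were called in the same direction, against a median of 20 and a 95% range of 12 to 29 in 10000 permutations (permutation p = 0.233, a test chosen after the data were seen). Both tests can miss a short stretch with changes in both directions. The X-linked Bex, Tceal and Armcx genes described below had 3 rises and 3 falls among 12 measured members.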

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

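The check of sex-linked RNA was planned, and each test of an explanation below was chosen only after its result was seen. Outside the main comparison, 4 arrays labelled female held Y-linked RNA. Of 3650 probe sets with several gene names or none, 47 were higher and 53 lower in DNMTs-Tg hearts, against 483 higher and 646 lower among all 27319 probe sets tested, so calls were not more frequent among them.

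The sex-linked RNA differed from the labels in the 3 DNMTs-Tg arrays and wild-type replicate 1. An inversion of all 6 sex labels is argued against, since 2 arrays would then differ from their labels. Male RNA mixed into RNA of females is argued against by Xist, which varied by 0.44 (log2) over the 5 arrays with Y-linked RNA and lay 5.15 below the array of wild-type replicate 4. Arrays exchanged between the genotypes are argued against by Dnmt3l, whose lowest DNMTs-Tg value lay 6.71 (log2) above the highest wild-type value. Wrong sex entries for 4 mice, or hearts of other mice of the same genotype, stay open and untested, and no biological explanation was tested.

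For the 735 genes changed between the genotypes, the other 9 of the 10 splits of the 6 arrays into 3 and 3 gave at most 0 genes and 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05. Most calls lying in a few stretches of chromosome, around an insertion site or from another strain, is argued against by the highest ratio of a chromosome's share of changed genes to its share of tested genes, 1.33 over 20 chromosomes, with exact 95% intervals that reach 1.86 at most. A short stretch that holds a small part of the calls is not covered by that ratio. For the sex of wild-type replicate 4 as the whole cause, that array was predicted to be the wild-type array farthest from the DNMTs-Tg arrays in nearly all 735 genes. It was so in 279, but this count cannot decide. A gene changed by that sex alone would leave the other wild-type arrays at the DNMTs-Tg level and would hardly be called. Without wild-type replicate 4 all arrays were of male type, and 52 rises and 110 falls were called, which argues against that cause for those genes. Leaving out wild-type replicate 4 ended 575 of the 735 calls, as 614 and 539 ended without wild-type replicate 1 or 6. The median absolute log2 change of the 575 went from 0.80 to 0.79 and their median SE, with fewer arrays, from 0.14 to 0.17. Without wild-type replicate 1 or 6 instead, the same 575 genes had median changes of 0.82 and 0.81 and median SEs of 0.17 and 0.16. The transgenes remain a candidate explanation, as do a partial effect of that sex difference, a difference in strain background across the genome and the higher Gapdh 3' to 5' difference of the DNMTs-Tg arrays, which were not tested.

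The extracellular matrix list was highest in DNMTs-Tg replicate 1, by 1.54 (log2) over replicate 6. RNA degradation in that array cannot be told apart, since its Gapdh 3' to 5' difference lay 0.033 (log2) above that of replicate 6 but 0.218 above that of replicate 5, where the wild-type SD was 0.061, and 3 arrays are too few to weigh these against each other. A larger share of otherwise unaltered fibroblasts as the whole cause is argued against only if fibroblasts alone express both sets of genes below, which was not tested. In that array 17 fibroblast markers outside the matrix list had a median log2 difference from wild-type of 0.42. For 25 matrix genes outside the fibroblast list it was 1.56, a gap with a 95% bootstrap interval over genes of 0.19 to 1.89. Genes are not independent replicates, with estimated correlations of 0.80 in the matrix list and 0.53 in the fibroblast list. That interval may therefore be too narrow, and it describes this heart only. A change within the fibroblasts or the macrophages of this heart stays open, and no biological explanation was tested because the design gives replicate 1 no group of its own.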

How the results depend on the processing

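All alternatives here were planned. No call changed sign for any of the 90 named genes. Of 803 values under settings other than leaving out an array, 697 kept their side of the threshold, 76 lost the call and 30 gained it. The replicate block made 59 of these losses and the array weights 25 of these gains, and both settings are questioned below. With 1 array left out, 374 of 540 kept it, 142 lost it and 24 gained it. The 306 rises and 429 falls stayed within 1.5 times under quantile normalization, a common median, either filter setting, the mean of a gene's probe sets, both variance models and each probe set with 1 symbol on its own. They became 768 and 887 (53.6% lower) at an adjusted p of 0.10, 132 and 193 at 2-fold, and 255 and 265 (51.0% lower) at unadjusted p under 0.05 with 2-fold. In all, 3543 genes had an unadjusted p under 0.05. Array weights gave 2328 and 2494 (51.7% lower), but their estimation did not converge and gave DNMTs-Tg replicate 5 a weight of 5.63 and replicate 1 one of 0.203, so its counts are not relied on. With the label number as a replicate block limma gave 1 rise (Dnmt3l) and 0 falls, with 1537 genes at unadjusted p under 0.05, a Dnmt3a change of 0.74 past no threshold and 16 lists. The 2 shared numbers belong to different mice and their arrays' deviations correlated at -0.054 and -0.080, so the arrays are not pairs, and the block leaves few degrees of freedom. With 1 array left out, rises ranged from 44 to 815, falls from 79 to 789, the share lower from 49.2% (without DNMTs-Tg replicate 6, which turned the majority) to 67.9% (without wild-type replicate 4). The Dnmt3a change ranged from 0.87 to 1.25 and lists past the threshold from 6 to 11, and the cause was not tested. Without DNMTs-Tg replicate 5 rises and falls were 50 and 92, without wild-type replicate 1 they were 44 and 79, without wild-type replicate 4 they were 52 and 110 and without wild-type replicate 6 they were 74 and 128. Dnmt3a also lost its call under quantile normalization (0.98), with no filter (1.02, more genes tested) and with the mean of its probe sets (0.050). The number of lists past the threshold, 7, became 12 with no filter, 0 with an estimated correlation and 1 by fry (DNA methylation machinery, which is not among the 7). The lists added with no filter were those of germline genes, ion channels, the integrated stress response, muscle atrophy and macrophages. Interferon was the only one of the 7 to lose its call with an array left out (adjusted p = 0.0524 without wild-type replicate 6, range 3.29e-07 to 0.0524). The chromosome test gave 0.923, and 0.794 at the looser threshold. Promoter CpG content was not run for lack of a genome, and the pseudocounts were not run because the values were log2 already. Without detection calls, falls to signal that was dim on every DNMTs-Tg array are bounds. The fall of Dcaf12l1, dim on all but DNMTs-Tg replicate 6, is uncertain in size.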

Other observations

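The families below were chosen after their values were seen, so their tests describe these arrays only. Glutathione S-transferase genes, whose products conjugate glutathione to reactive compounds, fell in 6 of 22 measured members and rose in 0, against 429 falls among 13634 genes (Fisher's exact test, 2-sided p = 4.55e-05). Besides Gstk1 these were Gstt2 (-1.98 ± 0.32, SE, adjusted p = 0.0193), Gstm5 (-1.67 ± 0.09, adjusted p = 0.000628), Gstm7 (-1.48 ± 0.11, adjusted p = 0.00151), Gstm4 (-1.45 ± 0.23, adjusted p = 0.0202) and Gstp1 (-1.02 ± 0.21, adjusted p = 0.0425). The family median was -0.27, with 6 falls under quantile normalization and 7 with a common median. The count ranged from 2 to 8 falls when 1 array was left out, and only Gstm5 and Gstm7 were called in each of those 6 fits. Related members can share probes on the array, so their falls may not be independent, which was not tested.

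The X-linked family of Bex, Tceal and Armcx genes split in both directions, with 3 rises and 3 falls among 12 measured members, as also under quantile normalization and with a common median (Fisher's exact test for any change, 2-sided p = 1.68e-05). With any 1 array left out 2 of the rises (Tceal7 and Armcx4) and 2 of the falls (Bex1 and Tceal1) were called. Besides Tceal7, Armcx4 rose by 2.05 ± 0.20 (SE, adjusted p = 0.00415) and Armcx3 by 0.99 ± 0.12 (adjusted p = 0.00751). Besides Bex1, Tceal1 fell by 1.48 ± 0.11 (adjusted p = 0.00155) and Tceal8 by 1.16 ± 0.21 (adjusted p = 0.0292).

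A control probe set for B1 repeat RNA, 1 of 64 control probe sets, had log2 signals of 9.70 ± 0.31 (SD, n = 3) in DNMTs-Tg and 10.84 ± 0.55 (SD, n = 3) in wild-type arrays, with no overlap (exact permutation test, 2-sided p = 0.1, the smallest possible). Groups also did not overlap for 34.9% of the genes tested and for the Gapdh 3' to 5' difference. The cause of the B1 difference was not tested.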
